A study of Mus musculus with 4 samples.

How the data were processed

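The series holds 4 samples, which per the labels are 1 RNA library and 1 chromatin library for each of 2 genotypes, WT and ΔORF, made from nuclei of frozen whole hearts of mice aged 2 months. Per the labels' protocols n = 3, and whether several hearts entered 1 library is not given in the sources used here. The design therefore has 1 library per genotype, and no test between genotypes was made from cells or nuclei.

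The deposited matrices hold raw counts, UMIs for each gene and cut ends for each peak in each called barcode. The fragment files hold, per the file headers, the output of Cell Ranger ARC 2.0.2 with an mm10 reference, 1 entry per fragment with its count of read pairs. Per the submitters' processing notes R 4.2.2, Seurat, Signac and MACS2 were used, with no role given for each, and no normalised values were used here. Cut ends recounted from the fragments matched the deposited peak counts in 82.8% of WT and 83.4% of ΔORF peaks, with a ratio of totals of 0.999 in the WT library. Of the barcodes called as nuclei, 27 were the same sequence in both libraries, and each library was kept apart.

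Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Of the deposited barcodes 815 WT and 1612 ΔORF had fewer than 500 UMIs, and 134 and 812 had more than 10% mitochondrial UMIs. Scrublet, as built into scanpy and run per library with an expected rate of 0.06, called 55 (2.05%) of 2685 WT and 13 (0.52%) of 2524 ΔORF nuclei as doublets, and these were left out. Both libraries were normalised to 10000 UMIs per nucleus and log-transformed, and clustered together without integration: 2000 variable genes, values clipped at 10, 30 principal components, 15 neighbours, Leiden resolution 1, seed 1. Clusters were named from 15 fixed marker lists by the type with the highest mean fold of its markers, when at least 3 of them were at least 2-fold over the other nuclei. A cluster was left unnamed when at least 5 markers of an unrelated type were raised too or more of them led it, when a non-cardiomyocyte cluster had cardiomyocyte markers at 25% of the cardiomyocyte level, or when 3 of 8 dendritic cell genes led it. These thresholds were set after the clusters were seen. Classes are called "like" because they rest on markers alone.

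UMIs were summed over the nuclei of a class and library and divided by the total of the class, as CPM. Levels carry exact Poisson intervals, shares exact binomial intervals and ratios exact conditional binomial intervals, all at 95%. Classes with at least 50 nuclei in each library were compared, for genes with at least 100 UMIs over both libraries in cardiomyocyte-like nuclei and 50 elsewhere, and genes at least 2-fold apart were counted by size. The number that counting error alone would give was computed from the binomial distribution with both libraries alike. The 21 gene lists were read as the median log2 ratio of members past the minimum, with its percentile among 10000 random lists of the same size drawn from 20 bins of expression, and as members at least 1.5-fold apart. At least 3 measured members were needed for a median. Lists marking other cell types were read as free RNA or mixed nuclei, and no such list had 3 measured members in cardiomyocyte-like nuclei.

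Genes were named by a rule of size. In cardiomyocyte-like nuclei these are the 12 highest and 12 lowest ratios among genes with at least 200 UMIs and at least 20 in the library where the gene is higher. Left out were mitochondrial and hemoglobin genes, the 6 genes of the sex-linked list, markers of other types and predicted genes. Other genes on chromosome X were not left out. Every member of the hypertrophy, cardiac transcription factor and GATA4 target lists and the 2 highest and 2 lowest members of each other list could be named too, and a few of these members are not reported here. In other classes these are the 5 highest and 5 lowest with at least 100 UMIs, leaving out cardiomyocyte markers, and for peaks the 6 highest and 6 lowest with at least 100 fragments on autosomes. List members outside cardiomyocytes, among them Col1a1, Col3a1 and Loxl2, quality markers, and leading genes of clusters were chosen after their values were seen.

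Fragments of cardiomyocyte-like nuclei, assigned by the barcode shared with the RNA, were counted over 61563 peaks merged from the 51432 WT and 43552 ΔORF peaks as deposited, and divided by the fragments in peaks. Peaks on autosomes with at least 50 fragments were compared. Peaks were given the nearest gene body, since the gene table carries no strand and start sites were not known. For the same reason accessibility near genes was read within 1 kb of the gene end with more fragments, in place of the planned start site, and within the gene body with 1 kb on each side. Gene positions are those of GRCm38.p6, the assembly mm10 stands for. The planned GATA motif share was not run because no genome sequence was at hand, and a split by sex was not possible, since too few fragments lay on chromosome Y to tell the nuclei apart and Xist was high in both libraries.

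The comparison was tested on simulated data drawn from Poisson rates of both libraries together, with 200 genes altered. Of 4967 genes run in cardiomyocyte-like nuclei, 50 of 50 genes made 3-fold higher and 35 of 35 made 3-fold lower passed 2-fold, while 2 of 50 made 1.5-fold higher did, and 0 unaltered genes passed. Intervals held the true ratio for 95.4% of genes. In fibroblast-like nuclei 17 unaltered genes of 5197 run passed 2-fold, and in macrophage-like nuclei 11 of 2674, so 2-fold counts in the smaller classes hold a part from counting error.

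The gene and marker lists, filters, naming rule, comparisons and most alternatives were fixed before the data were examined. Alternatives covered the UMI minimum of nuclei and genes, doublets, clustering, scaling by trimmed mean of M values (TMM) or median of ratios, thinning nuclei to 500 UMIs or 500 fragments in peaks, free RNA subtraction, atrial clusters, and the scaling, minimum and unit of peaks. Free RNA was estimated from barcodes under the UMI minimum at 10.0% of WT and 10.7% of ΔORF cardiomyocyte-like UMIs. These 815 WT and 1612 ΔORF barcodes had been called as nuclei. Their profile may therefore hold RNA of shallow nuclei beside free RNA, and values with free RNA subtracted share this limit. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.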

Results

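Nuclei from frozen whole hearts of wild-type (WT) and ΔORF mice, 2 months old, were profiled with a multiome assay, which reads RNA and transposase-accessible chromatin (ATAC) from the same nucleus. The series title ties the genotype to an upstream open reading frame, to translation of the cardiac transcription factor GATA4 and to cardiomyocyte size. The labels give 4 samples, which are 1 RNA library and 1 ATAC library per genotype. The protocol states n = 3 for the hearts. Whether hearts were pooled into each library is not given in the sources used here.

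The WT library held 3563 called barcodes with 4321362 RNA molecules (UMIs) and the ΔORF library 4473 barcodes with 4105701 UMIs. Filtering left 2630 WT nuclei with a median of 1059 UMIs and 2511 ΔORF nuclei with a median of 979 UMIs. The median mitochondrial share of these nuclei was 0.95% in the WT and 1.88% in the ΔORF library. Gm42418, a transcript annotated over ribosomal RNA sequence, stood at 11697 CPM (UMIs scaled to the library total) in the WT and 21411 CPM in the ΔORF library. The ATAC data held 49735064 WT and 61001632 ΔORF fragments, of which 40.2% and 33.6% carried the barcodes called as nuclei. With 1 library per genotype there was no test between genotypes, and every difference describes these 2 libraries. Intervals are exact 95% intervals and cover counting error only, not differences between animals or between preparations. All log2 ratios are ΔORF over WT.

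The question for cell composition was which cell classes of the heart the nuclei came from. Cardiomyocyte-like nuclei, atrial ones included, made up 36.1% (34.2 to 37.9) of WT and 38.8% (36.8 to 40.7) of ΔORF nuclei. The clusters within this class differed more. Cluster 1, the largest, held 17.57% of WT and 17.05% of ΔORF nuclei. Cluster 2 held 8.86% (7.80 to 10.01) and 14.02% (12.68 to 15.44), and cluster 7 held 8.10% and 4.70%. These clusters also differed in depth. Median UMIs of WT and ΔORF nuclei were 1865.5 and 1841 in cluster 1, 1062 and 1041 in cluster 2, and 3625 and 3406.5 in cluster 7. Median mitochondrial shares of WT nuclei were 0.69%, 1.17% and 0.40%. Whether depth or quality of nuclei set these clusters apart was not tested. Fibroblast-like nuclei made up 29.0% (27.3 to 30.8) and 25.1% (23.4 to 26.9), but with each library clustered by itself the order turned, with 24.4% of WT and 25.9% of ΔORF nuclei, where a WT cluster of 130 nuclei with fibroblast and Schwann cell markers stayed unnamed. Macrophage-like nuclei took a larger share of the ΔORF library, with 311 of 2511 nuclei or 12.4% (11.1 to 13.7) against 204 of 2630 or 7.76% (6.76 to 8.85). Vascular endothelial-like nuclei stood at 8.97% in the WT and 9.04% in the ΔORF library, and pericyte-like nuclei at 8.29% and 7.89%. Endocardial-like nuclei stood at 4.49% (3.73 to 5.35) in the WT and 2.91% (2.29 to 3.64) in the ΔORF library, and mesothelial-like nuclei at 1.22% and 0.48%. Lymphatic endothelial-like, smooth muscle-like and Schwann cell-like nuclei each made up less than 1% of both libraries.

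The higher macrophage-like share lay in 1 cluster. Macrophage-like cluster 9 held 124 ΔORF and 9 WT nuclei, and its leading genes were Cd72, Adgre1, Pou2f2, Fyb, Pik3r5, Prkcb, Itgam, Fcrls and Top2a. The other, cluster 6, held 187 ΔORF and 195 WT nuclei and was led by F13a1, Cd163 and Mrc1, genes of macrophages resident in tissue. Without cluster 9 the macrophage-like share was 7.44% in the WT and 7.83% in the ΔORF library. A cluster held mostly by 1 library may be a property of that library and not a cell type. With every barcode kept, which drops the UMI, gene and mitochondrial limits together, the cardiomyocyte-like share was 29.2% in the WT and 26.4% in the ΔORF library. Clusters left unnamed held 2.66% of WT and 2.31% of ΔORF nuclei, under thresholds for mixed clusters that were set after the data were seen.

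**Figure D1:**
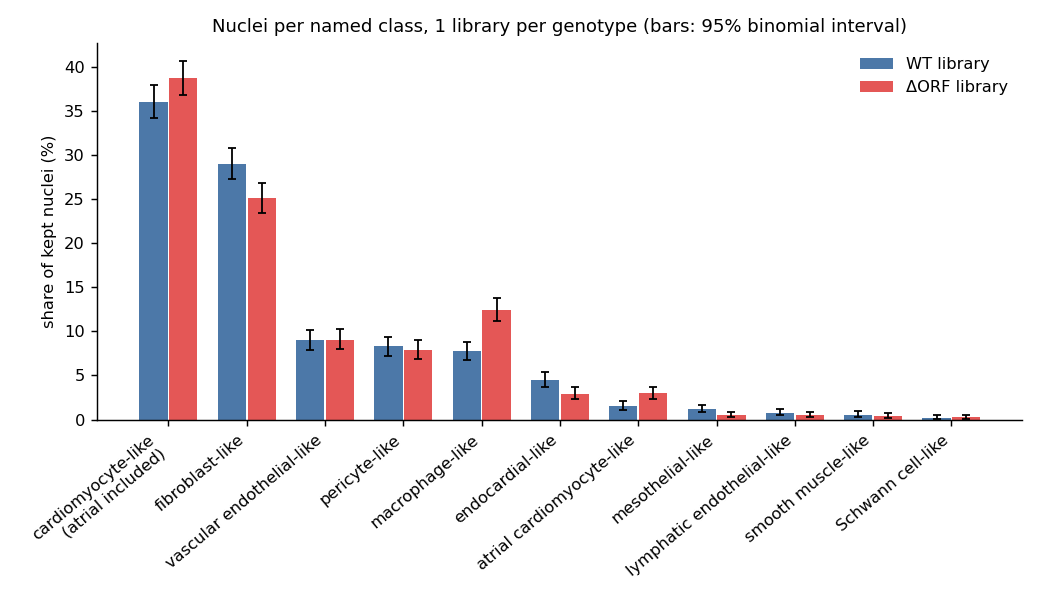
Share of kept nuclei (%, vertical axis) in each named class for the WT and ΔORF libraries, with exact 95% binomial intervals as error bars. Macrophage-like nuclei stand at 7.76% and 12.4%, and cardiomyocyte-like nuclei, atrial ones included, at 36.1% and 38.8%.

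Gata4 RNA itself stood at the same level in cardiomyocyte-like nuclei of both libraries. Gata4 (ENSMUSG00000021944, chromosome 14, 63198914 to 63271712 on mm10) encodes the zinc finger factor that drives cardiac gene programmes. It had 610 WT UMIs, or 288 CPM (266 to 312), and 526 ΔORF UMIs, or 293 CPM (269 to 319). The log2 ratio was 0.02 (−0.15 to 0.20). Translation of the transcript was not measured. Outside cardiomyocytes, Gata4 ratios were −0.22 (−0.66 to 0.21) in fibroblast-like, −0.12 (−0.91 to 0.65) in pericyte-like and −0.80 (−1.97 to 0.24) in endocardial-like nuclei. Macrophage-like nuclei had 13 and 11 Gata4 UMIs and vascular endothelial-like nuclei 5 and 3, too few to compare.

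Chromatin over Gata4 was also close in the 2 libraries. Fragments over the Gata4 gene body in cardiomyocyte-like nuclei had a log2 ratio of 0.13 (0.02 to 0.24), with a median of 0.06 over all measured genes. Of 12 peaks in Gata4 or within 20 kb of it, the interval of 1 excluded 0, a peak inside the gene at 63255540 to 63256442 with 84 WT and 38 ΔORF fragments and a ratio of −0.73 (−1.32 to −0.16). That peak was singled out after its values were seen.

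**Figure D2:**
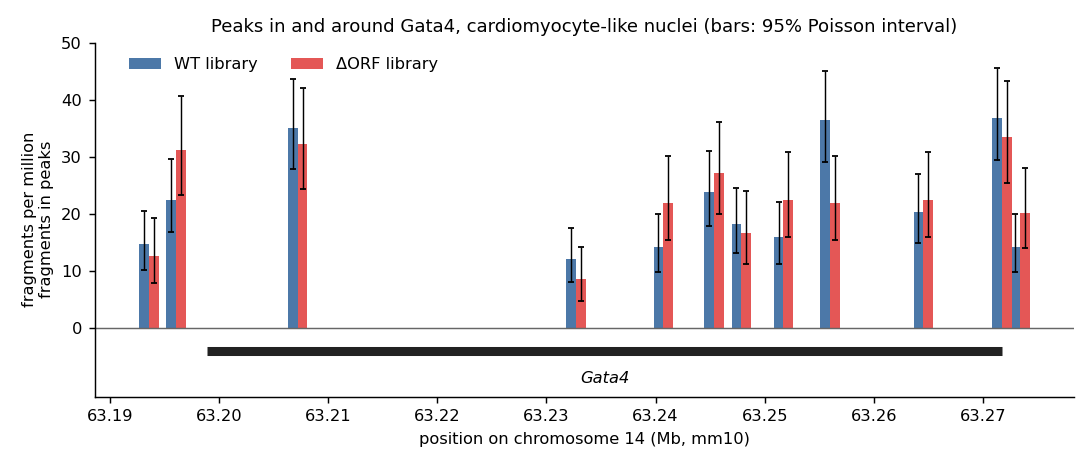
ATAC fragments scaled to the fragments in peaks (vertical axis) for the peaks in and around Gata4 in cardiomyocyte-like nuclei, along chromosome 14 (Mb, mm10), with exact 95% Poisson intervals. The peak at 63255540 to 63256442 stands at 36.4 in the WT and 21.9 in the ΔORF library.

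In cardiomyocyte-like nuclei, among genes with at least 200 UMIs ranked by the fixed rule, the lowest ratios were those of Irs2 and Ppargc1a and the highest those of Csf1, Kazn and Ankrd1. List members with fewer UMIs reached as high, with Nppb at 1.66, Nr1d1 at 1.47 and Eno1 at 1.24. Irs2 (ENSMUSG00000038894), an adaptor of insulin and IGF1 receptors, was the lowest, with 342 WT and 41 ΔORF UMIs and a log2 ratio of −2.82 (−3.33 to −2.35). Ppargc1a (ENSMUSG00000029167), the coactivator of mitochondrial biogenesis, followed with 3901 and 764 UMIs and a ratio of −2.11. Highest under the same limit were Csf1 (ENSMUSG00000014599), the macrophage growth factor, with 130 and 298 UMIs and 1.44 (1.13 to 1.74), and Kazn at 1.20 (0.84 to 1.57). Ankrd1 (ENSMUSG00000024803), the stretch-responsive cardiac ankyrin repeat protein, had 664 and 1290 UMIs and a ratio of 1.20 (1.06 to 1.33). These sums came from 2116113 WT and 1794641 ΔORF UMIs.

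The other genes with lower RNA in the ΔORF library were Rnf144b at −2.01, Fnip2 (a partner of folliculin) at −1.92, Nr4a1 (an immediate early nuclear receptor) at −1.78, Dhrs3 (a retinaldehyde reductase) at −1.60 and Ugp2 (which makes UDP-glucose for glycogen) at −1.60. They were followed by Tcp11l2 at −1.42, Slc25a33 (a mitochondrial pyrimidine nucleotide carrier) at −1.37, Optn and Bnip3 (both receptors of mitophagy) at −1.36 and −1.33, and the heart transcription factor Hand2 at −1.33 (−1.79 to −0.89). The other genes with higher RNA were the actin crosslinkers Flna and Flnc at 1.10 and 1.08, Caskin2 at 1.08, Ppp6r1 at 1.07, the imprinted gene Peg3 at 1.03, the titin cap gene Tcap at 0.93, the endoplasmic reticulum chaperone Hsp90b1 at 0.92, the fatty acid importer Cpt1a at 0.90 and the transferrin receptor Tfrc at 0.90. In cardiomyocyte-like clusters 1, 2 and 7, which held most of the class, the 12 lower genes all had ratios below 0 and the 12 higher genes all had ratios above 0. The genes were chosen by their ratios over this whole class, so the shared sign in these clusters was in part set by the choice. Clusters 11 and 12, which are small, were mixed: 7 and 9 of the lower genes lay below 0, and 8 and 4 of the higher genes above 0. Ppargc1a is a leading gene of cluster 7, which held 213 WT and 118 ΔORF nuclei, and its ratio within cluster 1, the largest, was −1.84.

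Several of these sizes depended on the nuclei used. In cluster 1 alone Flna stood at 0.53, Flnc at 0.64, Peg3 at 0.52, Tfrc at 0.52 and Bnip3 at −0.81. At a minimum of 1000 UMIs per nucleus Hand2 stood at −0.79, Cpt1a at 0.50 and Rnf144b at −3.04. This minimum left the class 907534 WT and 813286 ΔORF UMIs, from 2116113 and 1794641. Nuclei under 1000 UMIs could not hold that loss, so further nuclei left the class when clusters were made and named anew. Values at this minimum therefore come from another set of nuclei. With free RNA subtracted Caskin2 stood at 1.67. The subtraction left Flna no WT UMIs, so its value of 2.19 used a floor of 3 UMIs and is not a measured size. With nuclei thinned to 500 UMIs Caskin2 and Hsp90b1 both stood at 0.59.

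The chromatin of the same nuclei showed smaller differences with the same sign for most of these genes. Gene-body fragments gave −0.41 (−0.60 to −0.22) for Irs2, −0.34 (−0.39 to −0.28) for Ppargc1a, −0.44 (−0.56 to −0.32) for Fnip2 and −0.49 (−0.69 to −0.30) for Ugp2. For the 12 lower genes the median was −0.31 with 11 of 12 below 0, and Hand2 was the exception at 0.08 (−0.22 to 0.38). Ankrd1 stood at 0.63 (0.37 to 0.90), and the 11 measured of the 12 higher genes had a median of 0.17.

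**Figure D3:**
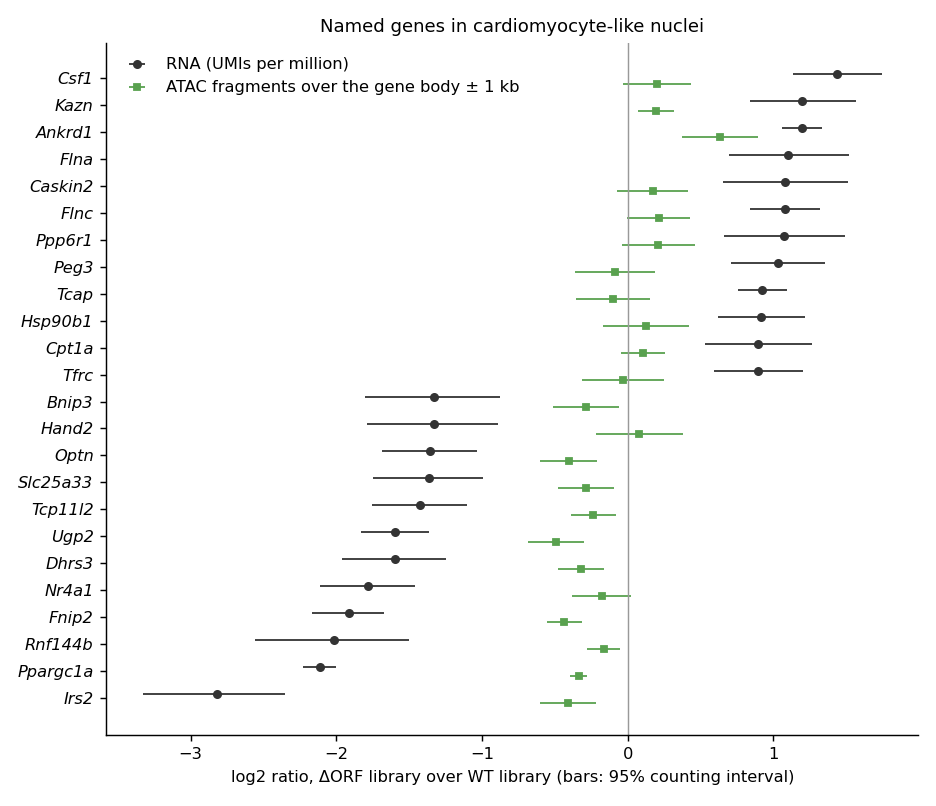
Log2 ratio, ΔORF over WT (horizontal axis), of RNA and of gene-body ATAC fragments for the 12 highest and 12 lowest genes with at least 200 UMIs in cardiomyocyte-like nuclei, with 95% counting intervals. RNA ratios run from −2.82 for Irs2 to 1.44 for Csf1, and the ATAC ratio lies below 0 for 11 of the 12 lower genes.

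By size, 32 of 4971 measured genes were at least 2-fold higher and 56 at least 2-fold lower in the ΔORF cardiomyocyte-like nuclei, where counting error alone would give 0.1 and 0.2. Median-of-ratios scaling gave 26 and 73. Nuclei thinned to 500 UMIs gave 9 and 21, the largest cluster alone gave 9 and 43, and weighting clusters alike gave 14 and 49. Fewer genes met the UMI minimum in thinned nuclei and in the largest cluster. Of the 32 and 56 genes, read without that minimum, 20 and 39 were still at least 2-fold apart in thinned nuclei. In the largest cluster 14 and 43 were, and with clusters weighted alike 14 and 46. Across genes the ratio ran against gene length, with a Spearman correlation of −0.264 over 4893 genes, which are not independent replicates.

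Hypertrophy and fetal genes lay on both sides of 0. The natriuretic peptide gene Nppb had 31 WT and 83 ΔORF UMIs and a ratio of 1.66 (1.05 to 2.30), Nppa had 114 and 166 UMIs and 0.78 (0.43 to 1.14), and Xirp2, an intercalated disc gene, had 0.48 (0.37 to 0.58). Fhl1, a sarcomeric stress sensor, was lower at −1.02 (−1.51 to −0.55), or −0.41 with thinned nuclei, as were Hopx at −0.40 and the calcineurin regulator Rcan2 at −0.36. Ccn2 at 0.43, Csrp3 at 0.13, the fetal myosin gene Myh7 at 0.12, Enah at −0.11 and Rcan1 at −0.21 had intervals across 0. Of the 12 measured members, Ankrd1 at 1.20 among them, 7 lay above 0, with a median of 0.12 at percentile 88.3 of random lists. At a minimum of 10 UMIs per gene 14 members were measured and the median was 0.28 at percentile 99.5. Nppa leads the 2 clusters that the marker rule named atrial, which made up 1.52% of WT and 2.99% of ΔORF nuclei. Cluster 11 held 29 WT and 38 ΔORF nuclei and had 6 of 6 atrial markers. Cluster 12 held 11 and 37 and had 3 of 6, and Cntn2 and Etv1, genes of the ventricular conduction system, were among its leading genes, so its atrial name is uncertain. In cluster 1 Nppa stood at 2.52 (0.95 to 4.52). Without the atrial clusters Nppa stood at 1.20 and the list median at −0.07, and with clusters weighted alike Nppa stood at 0.02.

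Genes described as GATA4 targets had ratios on both sides of 0. Actc1, cardiac actin, stood at 0.77 (0.67 to 0.86), Myl3 at 0.35, Myh6, the adult myosin heavy chain, at 0.34 (0.32 to 0.36), Tnnc1 at 0.32, Tnni3 at 0.22 and Vegfa at 0.09. Mef2c at 0.11 and Bcl2l1 at −0.16 had intervals across 0. The calcium pump gene Atp2a2 at −0.09, the sodium-calcium exchanger Slc8a1 at −0.25, the muscarinic receptor Chrm2 at −0.31 and Cryab at −0.45 lay below 0, the last at −1.08 at a minimum of 1000 UMIs per nucleus. The median of 16 members was 0.13 at percentile 93.1, and it was 0.03 with clusters weighted alike. With free RNA subtracted the list reached percentile 98.0, and at a minimum of 1000 UMIs per nucleus percentile 98.5. Slc8a1 stood at 0.06 in cluster 1. Among 15 cardiac transcription factors the median was −0.06 at percentile 39.6. Hand2, Esrrg at −0.76, Tbx20 at −0.72 and Tead1 at −0.57 were lower, and Zfpm2 at −0.21 and Prdm16 at −0.19 lay closer to 0. Gata6 at −0.20, Irx4 at −0.06, Myocd at 0.04 and Tbx5 at 0.15 had intervals across 0, while Mef2a at 0.12, Mef2d at 0.22 and Esrra at 0.38 (0.23 to 0.53) lay above it. Within cluster 1 Tbx20 stood at −0.33 and Tead1 at −0.36, and with thinned nuclei Tbx20 stood at −1.40.

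Of 19 lists measured in cardiomyocyte-like nuclei, 4 lay in the upper 2.5% of random lists and 0 in the lower 2.5%. Sarcomere genes were higher in the ΔORF library, with 23 of 28 above 0 and a median of 0.20 at percentile 99.9. Flnc and Tcap were the highest, at 1.08 and 0.93, and the M-band gene Myom2 at −0.75 and Mypn at −0.50 the lowest. The unfolded protein and stress response list had 5 of 6 members above 0 and a median of 0.55 at percentile 99.98, from the chaperones Calr at 0.93 and Hsp90b1 at 0.92 to Ddit3 at 0.22 and Herpud1 at −0.79. Glycolysis genes had 13 of 17 above 0 and a median of 0.25 at percentile 99.8, led by Eno1 at 1.24 and Eno3 at 0.82, while Pfkfb2, which sets the fructose 2,6-bisphosphate level, stood at −1.06 and Hk2 at −0.43. The glycolysis median was 0.06 with thinned nuclei, at percentile 76.7, and 0.13 in cluster 1. Eno1 stood at 2.08 (0.77 to 3.65) with thinned nuclei and at 0.67 (−0.12 to 1.48) in cluster 1, and Calr at 0.28 with thinned nuclei. With thinned nuclei the lists still in the upper 2.5% were sarcomere, with a median of 0.21, and mitochondrially encoded genes, and the stress response list had fewer than 3 measured members.

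Mitochondrially encoded genes made the remaining list and moved with the share of mitochondrial RNA in the library. All 12 were higher, with a median of 1.07, mt-Nd2 at 1.33, mt-Cytb at 1.31, mt-Co1 at 0.76 and mt-Atp8 at 0.57, and with free RNA subtracted the median was 0.50 and mt-Cytb stood at 0.62. Beside the sarcomere, glycolysis and stress lists, Gm42418 stood at 0.69 and AY036118 at 0.76 in these nuclei. Against random lists matched on gene length as well as expression, the percentiles were 98.7 for sarcomere, 98.5 for glycolysis, 99.9 for the stress response, 84.7 for hypertrophy and 84.0 for GATA4 target genes.

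Fatty acid oxidation genes had a median of 0.12 at percentile 95.8, with Ppargc1a and Ppara (−0.75) the lowest and Acadvl (0.72) and Acaa2 (0.64) the highest of 25 members. With thinned nuclei the median was −0.08 and Acaa2 stood at −0.04. The list lay in the upper 2.5% of random lists under 6 alternatives, from percentile 97.7 with doublets kept to 98.8 with at most 5% mitochondrial UMIs, and at percentile 84.9 among random lists matched on gene length as well. Nuclear-encoded respiratory chain genes stood at 0.04 (percentile 73.9), and at 0.22 (percentile 97.8) at a minimum of 1000 UMIs per nucleus, with Cox7c at 0.43 among the highest and Ndufs4 at −0.50 and Sdhc at −0.48 the lowest. Calcium handling and ion channel genes had a median of −0.17 at percentile 12.2, with Jph2, which anchors the dyad, and Kcnd2 both at −0.56, Kcnh2 at 0.56 and Gja1 at 0.18. That median was −0.02 in cluster 1. Translation and growth signalling stood at −0.08 (percentile 15.5), from Irs2 and Rheb at −0.74 to Eef1a2 at 0.55. Ribosomal protein genes stood at 0.20 (percentile 95.4), with Rpl4 at 1.11 and Rpl17 at 0.91 the highest and Rps3a1 at −0.29, or −1.02 in cluster 1, and Rpl3l at −0.21 the lowest of 14 measured members. At a minimum of 10 UMIs per gene 77 ribosomal protein genes had a median of 0.29 at percentile 99.98, and with at most 5% mitochondrial UMIs the list reached percentile 98.3, against 80.0 without atrial clusters. Circadian clock genes stood at −0.06 (percentile 30.5), with Nr1d1 at 1.47, Dbp at 0.81 and Npas2 at −0.85. This list pools genes that peak at different hours, so its median can hide a shift of hour. Genes peaking with Nr1d1 had a median of 0.07 and genes peaking with Arntl one of −0.85. Angiogenesis genes stood at 0.17 (percentile 91.2), with Angpt1 at 0.55, Nrp1 at 0.31, Vegfb at −0.09 and Hif1a at −0.39. The angiogenesis median was −0.06 in cluster 1, and Vegfb stood at 0.53 at a minimum of 1000 UMIs per nucleus. Immediate early and heat shock genes stood at 0.00 (percentile 49.8), with Nr4a1 and Hspa8 at −0.55 the lowest and Jun at 0.31 and Dusp1 at 0.24 the highest, the latter at 1.03 with free RNA subtracted, and in cluster 1 the 3 measured members had a median of −0.95. Apoptosis genes stood at −0.04 (percentile 41.8), with Bnip3 and Bcl2l1 the lowest and Mcl1 at 0.08 and Mdm2 at 0.38 the highest, and the median was 0.30 at a minimum of 1000 UMIs per nucleus. Cell cycle genes had 3 measured members, Cenpf at 0.81, Cdk6 at 0.30 and Ccnd3 at −0.46, at percentile 87.1. Extracellular matrix genes had 3, Ccn2, Col4a1 at 0.00 and Col4a2 at −0.03, at percentile 54.5, with Col4a1 at 0.91 in thinned nuclei and −0.60 in cluster 1. Nuclear long noncoding RNAs stood at −0.06 (percentile 47.6), from Neat1 at −0.31 to Kcnq1ot1 at 0.27, with Malat1 at −0.05, or 0.13 in cluster 1, and 18 cardiomyocyte markers at 0.06 (percentile 83.6). The interferon list had Stat2 alone, at 0.10, and the sex-linked list Xist at −0.08 and Tsix at −0.54.

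**Figure D4:**
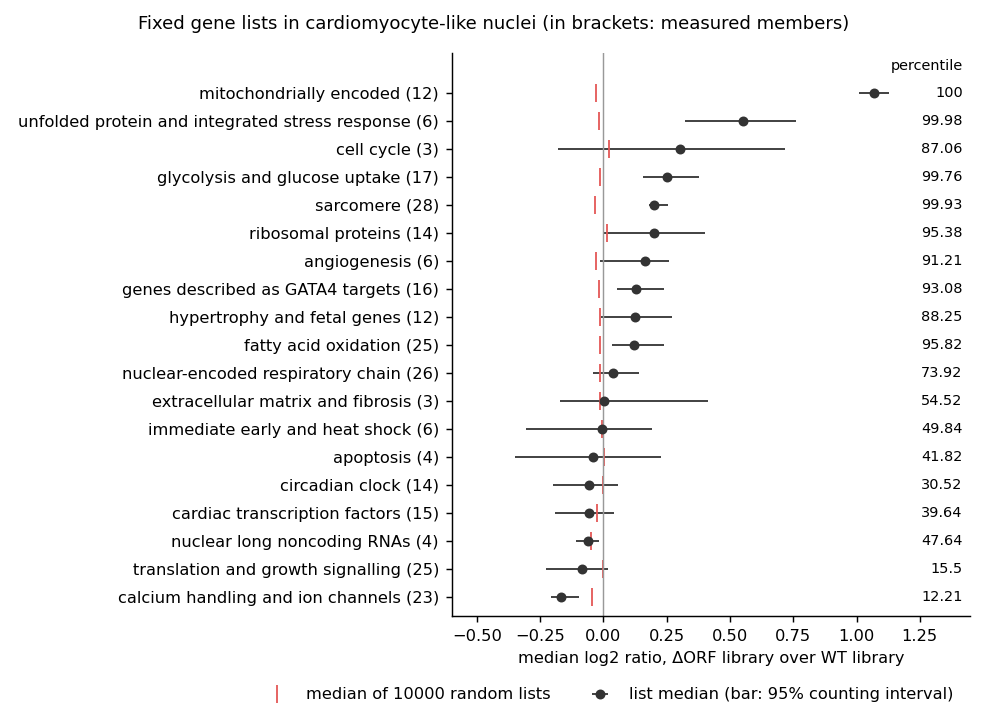
Median log2 ratio, ΔORF over WT (horizontal axis), of each fixed gene list in cardiomyocyte-like nuclei, with 95% counting intervals, beside the median of 10000 random lists matched on expression. The mitochondrially encoded list at 1.07 and the unfolded protein and stress response list at 0.55 are the highest.

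Open chromatin was compared in the same cardiomyocyte-like nuclei, which held 2306720 WT and 1732337 ΔORF fragments in peaks. The deepest difference among named peaks lay on chromosome 18 at 61484297 to 61485152, 6505 bp from Arhgef37, with 87 WT and 19 ΔORF fragments and a log2 ratio of −1.78 (−2.58 to −1.05). A peak in Ablim1, an actin-binding LIM protein gene, on chromosome 19 at 57271623 to 57272522 stood at −1.26 (−1.88 to −0.67), and the peaks nearest Gm27021, Zc3h4, Dhrs4 and Ier3 stood at −1.39, −1.23, −1.17 and −1.08. The highest peak lay in Zcchc17 on chromosome 4 at 130323013 to 130324251, with 40 and 64 fragments and 1.09 (0.50 to 1.70). Peaks in the Z-disc and stress fibre genes Palld at 1.08 and Pdlim5 at 1.07 followed, with those nearest Rfx7 at 1.08, Unc5d at 0.99 and Gm815 at 0.95. With nuclei thinned to 500 fragments Palld stood at 0.36 and Pdlim5 at 0.39, Zcchc17 at 2.18 and Unc5d at 2.01.

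Of 29960 peaks with at least 50 fragments, 128 were at least 2-fold more and 204 at least 2-fold less accessible in the ΔORF library, where counting error alone would give 45.6 and 83.3. At 200 fragments or more both counts were 0, so the peaks with the most reads differed by less than 2-fold. All-fragment scaling gave 73 and 335, counting cut ends 646 and 671, thinned nuclei 11 and 21, and the largest cluster 47 and 123. With cut ends the minimum of 50 applied to ends, which let in peaks with fewer fragments. Of the deposited peaks, 64.8% (64.3 to 65.2) of the WT and 76.4% (76.0 to 76.8) of the ΔORF set overlapped a peak of the other library. Among the upper 50% of peaks by cut ends these shares were 87.8% and 96.8%. Across 4338 genes, fragments near the gene end with more reads and RNA had a Spearman correlation of 0.06, and gene-body fragments over 4754 genes gave 0.18.

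Fibroblast-like nuclei of the ΔORF library had more RNA of the extracellular matrix genes. Postn, a matricellular protein of activated fibroblasts, had 46 WT and 111 ΔORF UMIs and a log2 ratio of 1.66 (1.15 to 2.19). The lysyl oxidase gene Loxl2 stood at 1.22 (0.51 to 1.96), Col1a1 at 0.81 (0.37 to 1.26) and Col3a1 at 0.50 (0.27 to 0.73), while Col8a1 at −0.13 and Mmp2 at −0.23 were the lowest. Of 25 matrix genes 22 lay above 0, 5 were at least 1.5-fold higher and 0 at least 1.5-fold lower, and the median of 0.36 exceeded those of all 10000 random lists. The proteoglycan gene Vcan, a leading gene of cluster 4, was higher at 1.01 (0.70 to 1.33). Cluster 4 held 201 WT and 227 ΔORF nuclei and cluster 0, the other fibroblast-like cluster, 562 and 404. Within cluster 0 the matrix median was 0.32, Vcan stood at 0.93 and Postn at 3.20 (1.43 to 5.60). With each library clustered by itself Postn stood at 2.91, but there a WT cluster with fibroblast and Schwann cell markers was left out of the class.

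Genes lower in ΔORF fibroblast-like nuclei were led by the nucleotide transporter Slc17a9 at −1.52 (−2.17 to −0.90), or −2.30 at a minimum of 1000 UMIs per nucleus, Dennd5b at −1.18, the glucocorticoid-induced cochaperone Fkbp5 at −1.14 (−1.44 to −0.85) and Tnks and the cystine carrier Slc7a11, both at −1.13. Ribosomal protein genes had a median of 0.26 and the stress response list 0.49, at percentiles 99.7 and 99.9. These moved to 0.13 and 0.28 with thinned nuclei, where neither lay in the upper 2.5%. Cardiomyocyte transcripts and mitochondrial RNA moved with this class: cardiomyocyte markers had a median of 0.93, sarcomere genes 0.95 and mitochondrially encoded genes 0.76. With doublets kept the marker and sarcomere medians were both 0.52, and with every barcode kept the sarcomere median was 0.62 and the mitochondrially encoded one 1.27. Nexn and Fhl2, muscle genes that stood at 1.05 and 1.11, and Erbb4 at 1.08 were among the 5 highest. With doublets kept Nexn and Fhl2 stood at 0.26 and 0.18. With each library clustered by itself, again without the WT cluster with fibroblast and Schwann cell markers, Erbb4 stood at 2.76 (1.94 to 3.69). Cardiac transcription factors had a median of 0.10 and genes described as GATA4 targets 0.12, the latter with Myh6 at 1.34 and Actc1 at 1.13. By size 27 genes were at least 2-fold higher and 55 lower of 5194, where counting error alone would give 6.4 and 10.9.

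Part of the difference in macrophage-like nuclei lay in cluster 9. Cd72, Itgam, Pou2f2 and Fyb, which lead that cluster, and Arhgap4 had ratios from 1.79 to 2.86 over the whole class. Without cluster 9 they stood at 0.99, 1.14, 1.11, 0.94 and 1.64, and 22 genes were at least 2-fold higher and 37 lower, against 81 and 73 with it. The lower genes were Fkbp5 at −1.85 (−2.38 to −1.34), Cyth1 at −1.80, Ccnd3 at −1.50, Got1 at −1.46 and Ebf1 at −1.25, and without the cluster Fkbp5 stood at −1.38. With the highest 6% of doublet scores left out Ebf1 stood at −0.43 and Got1 at −2.14. Cell cycle genes had a median of 1.38 over 5 members, with Cenpe at 2.41, Mki67 at 2.13, Top2a at 1.38, Cdk6 at −0.62 and Ccnd3 at −1.50. With the highest 6% of doublet scores left out that median was 0.09 (−0.35 to 0.54). Median-of-ratios scaling raised the ratios of this class, with a median over genes of 0.09 in place of −0.03.

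In macrophage-like nuclei interferon response genes had a median of −0.68 at percentile 0.32, with Oasl2 at −0.95, and −0.43 without cluster 9. Circadian clock genes stood at −0.55, with all 7 below 0 and Per3 at −0.74 the lowest, and at −0.20 without it. Immediate early genes stood at −0.50, with Klf4 at −1.34 and Klf2 at −1.10, and at −0.84 without cluster 9. Glycolysis genes stood at 0.62, with Gpi1 at 0.77, and at 0.70 without it. Mitochondrially encoded genes stood at 0.96. Sarcomere genes stood at 0.26, at 0.62 without it, at 1.77 (1.29 to 2.40) over 4 members with the highest 6% of doublet scores left out, and at 0.05 with doublets kept and 0.02 at Leiden resolution 2. Fibroblast, endothelial and pericyte markers stood at −0.65, −0.58 and −0.88, and at −0.24, −0.31 and −0.19 without it. The stress response list stood at 0.50, with Hspa5 at 1.34, and had fewer than 3 measured members without the cluster.

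Vascular endothelial-like nuclei of the ΔORF library had less Bmp6, an angiocrine factor of iron balance, at −1.54 (−2.04 to −1.07), less Fmo2 at −1.38, and less of the endothelial gene Rhoj at −1.23 (−1.67 to −0.81), Slc38a2 at −1.16 and Ccnd3 at −1.06. Immediate early and heat shock genes had a list median of −0.66 over 5 members, with Dusp1 at −1.35 and Klf4 at −0.71, while Klf2 at −0.44 had an interval across 0. Ribosomal protein genes had a median of 0.75 over 14 members and matrix genes 0.46, with Col15a1 at 0.79 and Col4a1 at 0.50. The highest named genes, Cmss1 at 1.31, Lars2 at 1.20, Cdk8 at 0.94 and Camk1d at 0.85, stood beside Gm42418, which had a ratio of 1.22 and reached 76693 CPM in ΔORF nuclei against 32984 CPM in WT. With at most 5% mitochondrial UMIs Cdk8 stood at 0.40 and Camk1d at 0.39. Myl2, a ventricular myosin light chain gene, stood at 0.75 beside cardiomyocyte markers at 0.36. With a mixed cluster added Myl2 stood at 0.37 and the markers at −0.27 (−0.48 to −0.08), and with each library clustered by itself they stood at 1.64 and 2.30. With every barcode kept Myl2 stood at 1.39, and with the highest 6% of doublet scores left out the markers stood at 1.52. TMM scaling raised the ratios of this class, with a median over genes of 0.03 in place of −0.13.

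Pericyte-like and endocardial-like nuclei, as named here, carried more cardiomyocyte RNA in the ΔORF library. In pericyte-like nuclei 32 genes were at least 2-fold higher and 29 lower of 1361, where counting error alone would give 2.7 and 4.2. Ttn stood at 2.01, Myh6 at 2.55 and the cardiomyocyte marker list at 2.29, and Fhl2, a cardiomyocyte gene, at 1.66. The direction of the marker list turned with every barcode kept, to −0.28 (−0.70 to −0.05), where Fhl2 stood at 0.42 and Auts2, the lowest gene of the class, had an interval of −1.51 to −0.51. With doublets kept the marker list stood at 0.70 and Fhl2 at 0.46, and with the highest 6% of doublet scores left out Fhl2 stood at −0.08, while it stood at 3.47 with each library clustered by itself and at 3.52 with at most 5% mitochondrial UMIs. The genes lower in this class were Auts2 at −1.78, Ptpn9 at −1.33, the GATA-type repressor Trps1 at −1.22, Exoc6b at −1.14 and Tbc1d5 with 79 WT and 31 ΔORF UMIs, and Lars2 at 1.06, Cmss1 at 0.84, Chd2 at 0.78 and Rbm25 at 0.75 were higher beside mitochondrially encoded genes at 1.16. In endocardial-like nuclei Ttn, Tnnt2 and Myh6 stood at 3.28, 3.42 and 3.53, and 13 genes were at least 2-fold higher and 25 lower of 665, where counting error alone would give 1.4 and 4.6. The sarcomere and cardiomyocyte marker medians of this class, both 3.42, were both 2.13 with every barcode kept and 2.18 at a minimum of 10 UMIs per gene. Bmx, a tyrosine kinase and leading gene of that cluster, was higher at 1.15 (0.71 to 1.59), followed by Palm, Csgalnact1, Smc4 and Ldb2 from 0.69 to 0.75. Lower were Tmtc2 at −1.81, Magi3 at −1.33, the glypican gene Gpc6 at −1.32, Abi1 at −1.23 and Rhoj at −1.17. Gpc6 stood at −0.70 with doublets kept and Tmtc2 at −0.90 (−1.55 to −0.27) with every barcode kept.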

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

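The tests of cluster mix, of RNA quality for the 12 lower genes, of a shift of all macrophages and of another tissue were chosen after the result was seen. The tests of hour of collection, of doublets and of the sarcomere list were written before.

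Many fragments were not used by the comparisons, and whether they hold a signal was not tested. Barcodes not called as nuclei carried 59.81% of WT and 66.42% of ΔORF fragments, and 10.25% and 8.94% of those fragments lay in peaks. Of the fragments of called barcodes 21.89% and 18.6% did. The circadian clock list had a median log2 ratio of 0.50 in endocardial-like nuclei, from 4 measured genes, and of −0.55 in macrophage-like nuclei, from 7. The macrophage-like median was −0.20 (−0.55 to 0.01) without cluster 9 and −0.13 (−0.72 to 0.28) with nuclei thinned to 500 UMIs, so the contrast between these classes rests in part on that cluster.

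The 12 genes lowest in ΔORF cardiomyocyte-like nuclei, Irs2 and Ppargc1a first, were weighed against 3 explanations. A different mix of cardiomyocyte-like clusters is argued against by the median of −1.56 inside the largest cluster, whose nuclei were among those the genes were chosen from. RNA capture or RNA quality as the only cause met the outcome set as evidence against it. Gene-body accessibility of the same genes, which comes from DNA, lay at percentile 0 of random sets. Its median of −0.305 was smaller than the RNA differences and was not read within clusters, so a part from RNA capture or RNA quality stays open. The hour of tissue collection stays open. Genes peaking with Nr1d1 minus genes peaking with Arntl came to 0.92 in cardiomyocyte-like, −0.10 in fibroblast-like and pericyte-like and −1.05 in vascular endothelial-like nuclei. These values met the outcome set beforehand as evidence against it. That outcome was ill chosen for pericyte-like and vascular endothelial-like nuclei, where the Arntl group had 1 gene with 20 UMIs or more. In cardiomyocyte-like and fibroblast-like nuclei, which differ in sign, the group had 5 and 3 such genes, too few to settle it with 1 library per genotype. Genotype remains an untested explanation beside these.

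Macrophage-like cluster 9, held mostly by the ΔORF library, was weighed against 3 explanations, of which doublets are argued against by a median doublet score at percentile 40.3 of the library and by UMIs 1.21 times those of the other cluster. A shift of all macrophages in the ΔORF library stays open. Inside cluster 6 the leading genes of cluster 9 had a median log2 ratio of 0.94 (0.57 to 1.07), with 6 of 9 measured above 0 and 3 below. These genes were picked over nuclei of both libraries, so a difference between the libraries may have helped to pick them. Genes higher in cluster 9, chosen in 1 part of the ΔORF nuclei of cluster 6 and measured in the other part, avoid this. They had medians of −0.01 and 0.13 with members on both sides of 0. Macrophages of another tissue stay open too. Only 1 marker of such a tissue passed, Garnl3 of peritoneal macrophages, which met the outcome set as evidence against them, but most markers had too few UMIs to count. Timd4 of Kupffer cells, with 3 UMIs in cluster 9 and 37 in cluster 6, stood at −2.06 (−4.40 to −0.40) in cluster 9 over cluster 6. Nuclei with at least 3 UMIs of cell cycle genes made up 21.8% (14.9 to 30.1) of the ΔORF nuclei of cluster 9 against 1.6% (0.3 to 4.6) of those of cluster 6, and 55.6% (21.2 to 86.3) of the 9 WT nuclei of cluster 9. At Leiden resolution 2 a cluster led by Cd72 held 0 WT and 95 ΔORF nuclei and the one led by Top2a and Mki67 held 8 and 30, and genotype was not tested.

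The higher sarcomere list in ΔORF cardiomyocyte-like nuclei was weighed against 3 explanations. Short genes favoured in the ΔORF library are argued against by percentile 98.73 among random lists matched on gene length. Free RNA stays open: the median was 0.21 after its subtraction, which met the outcome set beforehand as evidence against it. However, the subtraction was scaled only on markers of other cell types, and its profile came from barcodes called as nuclei. Sarcomere genes were higher in every other compared class too, with medians from 0.26 in macrophage-like to 3.42 in endocardial-like nuclei. RNA quality of the ΔORF library stays open and met its test: gene-body accessibility of the list lay at percentile 93.53, inside the range of random sets, so DNA of the same nuclei did not set the list apart. Genotype is a further explanation, which was not tested.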

How the results depend on the processing

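Alternatives chosen after the results were seen are the 5% mitochondrial limit, the highest 6% of doublet scores left out, scaling without mitochondrial genes, Gm42418 and AY036118, the largest cardiomyocyte-like or fibroblast-like cluster alone, clusters weighted alike, the macrophage-like cluster left out, the mixed endothelial cluster added and the gene-body window. All others were planned.

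The Gata4 log2 ratio in cardiomyocyte-like nuclei ran from −0.07 to 0.14 over the settings, and the 32 higher and 56 lower genes kept their sign in every setting, except for 1 of each once free RNA was subtracted. Of 1937 values of named cardiomyocyte genes under alternatives 145 moved by more than their counting interval and 30 changed sign, 0 of them for genes at least 2-fold apart. Among the 30 were Malat1 (−0.05), at 0.13 in the largest cluster and 0.09 with clusters weighted alike, Vegfb (−0.09), at 0.53 with 1000 UMIs, and Acaa2 (0.64), at −0.04 thinned. Of 300 cardiomyocyte list medians 34 moved and 15 changed sign, 0 of them for the mitochondrially encoded list, the only list at least 1.5-fold apart. Among the 15 were hypertrophy genes, at −0.07 without atrial clusters, fatty acid oxidation, at −0.08 thinned, angiogenesis, at −0.06 in the largest cluster, and cardiac transcription factors and apoptosis, at 0.08 and 0.30 with 1000 UMIs.

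With every barcode kept, the cardiomyocyte-like share was 29.22% in the WT and 26.43% in the ΔORF library, the macrophage-like WT share 9.12%, the fibroblast-like shares 24.25% and 17.91%, and the cardiomyocyte marker median in pericyte-like nuclei reversed to −0.28. At 1000 UMIs the cardiomyocyte-like shares were 27.42% in the WT and 36.97% in the ΔORF library, with nuclei lost from that class in clustering as well as by the limit. The fibroblast-like shares were 20.9% and 15.96%, and the macrophage-like shares 0% and 0%, because the macrophage-like clusters stayed unnamed. Clustering each library by itself gave fibroblast-like shares of 24.41% in the WT and 25.85% in the ΔORF library, which turns their order, Leiden resolution 2 a macrophage-like WT share of 6.46%, and the 5% mitochondrial limit a cardiomyocyte-like ΔORF share of 40.78%. With the highest 6% of doublet scores left out the macrophage-like shares were 5.84% and 10.19%, and Fhl2 in pericyte-like nuclei reversed to −0.08. Without cluster 9 the macrophage-like ΔORF share was 7.83%.

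Nuclei thinned to 500 UMIs gave 9 genes at least 2-fold higher, 21 lower and 2 lists in the upper 2.5%, where fewer genes met the UMI minimum. A minimum of 400 UMIs per gene gave 11, 14 and 2, where fewer genes were compared, and a minimum of 10 UMIs gave 499 and 490, where counting error is largest. The largest cardiomyocyte-like cluster gave 9 higher genes and clusters weighted alike 14. Reciprocal overlap of 50% gave 64.14% of WT and 75.74% of ΔORF peaks, and the upper 50% of peaks by cut ends 87.84% and 96.78%. Peaks at least 2-fold more and less accessible numbered 73 and 335 scaled by all fragments, 0 and 0 at a minimum of 200 fragments, 646 and 671 as cut ends, 11 and 21 thinned, and 47 and 123 in the largest cluster. Scaling by all fragments lowered every ratio alike, because 26.63% of WT and 24.8% of ΔORF fragments lay in peaks. For cut ends the minimum of 50 applied to ends, so peaks with fewer fragments and more counting error were compared. The gene-body window gave a correlation of 0.18. Where no reason is given, the cause was not tested.

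No paired analysis was possible because each genotype has 1 library. The GATA motif share with its alternatives, the split by sex and leaving out a replicate were not run, for want of a genome sequence, of chromosome Y fragments and of replicates.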

Other observations

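The values and the test in this part were chosen after the results were seen. Genes that answer to glucocorticoids stood lower in several classes of the ΔORF library. Fkbp5, a cochaperone induced by glucocorticoids, had log2 ratios of −0.67 in cardiomyocyte-like, −1.14 in fibroblast-like, −0.95 in vascular endothelial-like, −0.32 in pericyte-like and −1.85 in macrophage-like nuclei. Tsc22d3 stood at −0.14, −0.86 and −0.64 in the first 3 of these and at −1.34 in macrophage-like nuclei. Zbtb16 lay below 0 in all 5 classes, from −0.40 to −1.03. Other genes read beside these were less uniform. Per1 stood at 0.41 in pericyte-like nuclei and below 0 in the other classes. Dusp1 stood at 0.24 in cardiomyocyte-like nuclei and below 0 in fibroblast-like, vascular endothelial-like and macrophage-like nuclei. Ddit4, read in fibroblast-like nuclei only, stood at 0.13. A hypothesis is that the glucocorticoid or fasting state of the animals differed and lowered genes that answer to it, Irs2 among them. Irs2 stood at −2.82 in cardiomyocyte-like but at −0.16 in fibroblast-like nuclei. The list lay in the lower 2.5% of random lists in 3 of 5 classes, with medians of −0.35 in cardiomyocyte-like, −0.60 in vascular endothelial-like and −0.60 in macrophage-like nuclei. In fibroblast-like and pericyte-like nuclei the medians were −0.16 and −0.41, at percentiles 12.5 and 3.32, so the test left the hypothesis open, and genotype and state cannot be told apart with 1 library of each.

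Single clock genes differed between classes. Nr1d1 stood at 1.47 in cardiomyocyte-like and 0.40 in fibroblast-like nuclei, and Npas2 at −0.85 and 1.02.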
